A study of Mus musculus with 20 samples.

How the data were processed

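Gene expression was measured by RNA sequencing of neurospheres from adult mouse spinal cord, with YAP1-depleted (KO) and wild-type (WT) cells in proliferation and in differentiation. Libraries were stranded poly(A) libraries (dUTP method) sequenced on a DNBSEQ instrument, per the labels' protocols. The labels name 20 samples, 5 in each of 4 groups, numbered 4 to 8. The deposited table of the series holds columns for 8 of them, replicates 7 and 8 of each group, and the other 12 labelled samples were not analysed here. It also holds 12 per-library columns of 4 libraries whose names match no label, and these were not used.

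The values analysed are the authors' estimated counts per gene (expected counts, some of them not whole numbers), not normalised. Totals per library ranged from 18075595 to 18940983. The aligner and the counting tool are not given in the sources used here, and whether counting used the strand is not stated. The submitters' processing notes name the genome GRCm39, while gene positions in the deposited table are those of GRCm38, since 85.4% of 16878 genes matched by gene ID have the same start as in the RefSeq annotation of GRCm38.p6. Coordinates are given as deposited, in GRCm38, and the exon of Yap1 was taken from GENCODE M21, also GRCm38. The deposited table also holds the authors' log2 fold changes and the q-values of their DESeq2 comparisons, per the file headers. These are printed only as values of the authors' deposited table. The table lists 16927 genes and 1 line without a gene, which was left out. Genes in families with near-identical copies, such as ribosomal protein genes, can share reads with those copies.

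Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr on the 4 groups, which kept 13046 genes (77.1%). Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust glmQLFit, TMM normalisation) in R 4.3.3, two-sided. It used 1 model with a term per group over the 8 libraries (4 residual degrees of freedom), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The biological coefficient of variation was 24.1%. The design fixed in advance foresaw all 20 libraries, and it was applied to the 8 analysed. Each contrast compared KO with WT within a condition or differentiation with proliferation within a genotype, and a further contrast tested the difference between both KO effects. CPM values are counts scaled to the TMM-adjusted size of each library, and group values are means with the SD over 2 libraries. With 2 libraries per group, a permutation of labels within a comparison cannot give a p under 0.05, and no test for outlying libraries was run within groups, although limma-voom with quality weights gives such libraries less weight. Folds against a group with no counts use a floor of 3 counts over the group, and groups with 1 to 3 counts are given as a ratio with a 95% counting interval.

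The groups, the tests, 27 gene lists and the rule for named genes were chosen before the data were examined. Yap1 and Wwtr1 were named in every library. For each pairwise comparison the rule took the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between libraries. Unnamed gene models and sex-linked genes were passed over (1 in all). Where none passed in a direction it took the 5 with the smallest p. It added up to 4 members of each list with the smallest p, of which the text gives a selection, and the values of some genes are not reported here. For the difference between KO effects it took genes only among those that passed, and none did. The lists cover cell type markers, the YAP/TAZ-TEAD signature, signalling pathways, the cell cycle, matrix, metabolism and Hox genes, and 25 of them had at least 3 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Calls were repeated with an estimated correlation and with fry. A call lost with an estimated correlation need not mean that the members vary together. For ependymal markers in KO against WT in proliferation the estimate was 0.00632, below the preset value. Their unadjusted camera p still rose from 1.9e-05 to 0.0123. In the simulated data described below, a list of 20 genes raised 1.5-fold passed with an estimated correlation in each pairwise comparison (camera adjusted p from 0.0274 to 0.0485). It did not pass for the difference between KO effects (0.471). Simulated genes varied independently of each other, while cholesterol synthesis genes had an estimated correlation of 0.694 in the data. Smaller shifts of a list were not simulated. These passes therefore do not show that a list call lost in the data means no shift. Gene Ontology terms came from the annotation columns of the deposited table (15 to 400 tested genes per term), with the same test.

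The edgeR test was tested on simulated data with 2 libraries per group and 200 changed genes. Simulated libraries were drawn independently, without the deviation that same-numbered libraries share in the data. The adjustment is also stricter where fewer genes change, so the shares below need not hold for the data. In KO against WT it recovered 78.8% (proliferation) and 71.2% (differentiation) of genes changed 4-fold, 47.8% and 34.3% of genes changed 2-fold, and 4.48% and 2.99% of genes changed 1.5-fold, with 8 false calls among 13036 genes and 6 among 13011. In differentiation against proliferation it recovered 77.3% (WT) and 72.7% (KO) at 4-fold, 35.8% and 41.8% at 2-fold, and 1.49% and 2.99% at 1.5-fold, with 5 false calls among 12609 genes and 4 among 12621. For the difference between KO effects it recovered 59.1% at 4-fold, 2.99% at 2-fold and 0% at 1.5-fold, with 2 false calls among 13025 genes. DESeq2 1.42.0 made 48, 46, 46, 53 and 33 false calls among 16580 genes in the same 5 simulations. For KO against WT in the data it called 6 genes higher and 5 lower in proliferation, and 4 and 34 in differentiation. The simulated number of false calls therefore cannot be carried over to the data.

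Alternatives were DESeq2, other normalisation factors (RLE or library totals alone), no filter or stricter filters on low counts and a replicate block on the sample number. Further ones were a fit of only the 2 groups compared, a test against a fold of 1.5, limma-voom with and without quality weights, and leaving out each library in turn. In a fit that leaves a group with 1 library, that library is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.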

Results

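RNA was sequenced from neural stem cells of the adult mouse spinal cord, grown as neurospheres. The model uses a Yap1 gene whose exon 3 can be removed by Cre recombinase, and Cre was delivered with an adenovirus. Cells with depleted YAP1 (KO) and wild-type cells (WT) were collected after 7 days of growth with EGF, FGF2 and heparin (proliferation) or after 5 days of differentiation. The labels name 20 samples in 4 groups of 5, of which 8 libraries were analysed here, replicates 7 and 8 of each group, so that n = 2 in every group. The other 12 labelled samples were not analysed here, and the labels do not state whether the WT cells received a virus or carried this Yap1 allele. If they did not, an effect of the virus or the allele cannot be told apart from loss of YAP1 in KO against WT. Total counts were 18940983 and 18448939 in WT proliferation (replicates 7 and 8) and 18356095 and 18075595 in KO proliferation. They were 18217134 and 18538656 in WT differentiation and 18204299 and 18420299 in KO differentiation. Of 16927 genes listed, 318 had no count in any of the 8 libraries and 13046 were tested. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

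Yap1, the targeted gene (gene ID 22601, chromosome 9, 7931999 to 8009565, GRCm38), encodes a transcriptional co-activator restrained by the Hippo pathway. Its normalised read count was lower in each KO library than in each WT library of the same condition. In proliferation it was 170.5 and 150.4 CPM (counts scaled to library size) in WT replicates 7 and 8, and 27.04 and 32.71 CPM in the KO replicates. In differentiation it was 106.8 and 93.69 CPM in WT and 22.59 and 27.79 CPM in KO. KO libraries thus kept 18.6% of the WT mean in proliferation and 25.1% in differentiation. Counts cover the whole gene, while the deletable exon 3 (7973796 to 7973911 in the transcript Yap1-202) spans 116 bp, so a residual count need not come from intact transcripts. Wwtr1, which encodes TAZ, the paralog of YAP1 (gene ID 97064, chromosome 3, 57455644 to 57575910), stood at 96.76 ± 6.02 CPM (SD, n = 2) in WT proliferation and 102.9 ± 5.96 CPM (SD, n = 2) in KO proliferation. In differentiation Wwtr1 stood at 105.6 ± 11.8 CPM (SD, n = 2) in WT and 71.87 ± 4.9 CPM (SD, n = 2) in KO, which is 68.1% of the WT mean.

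**Figure D1:**
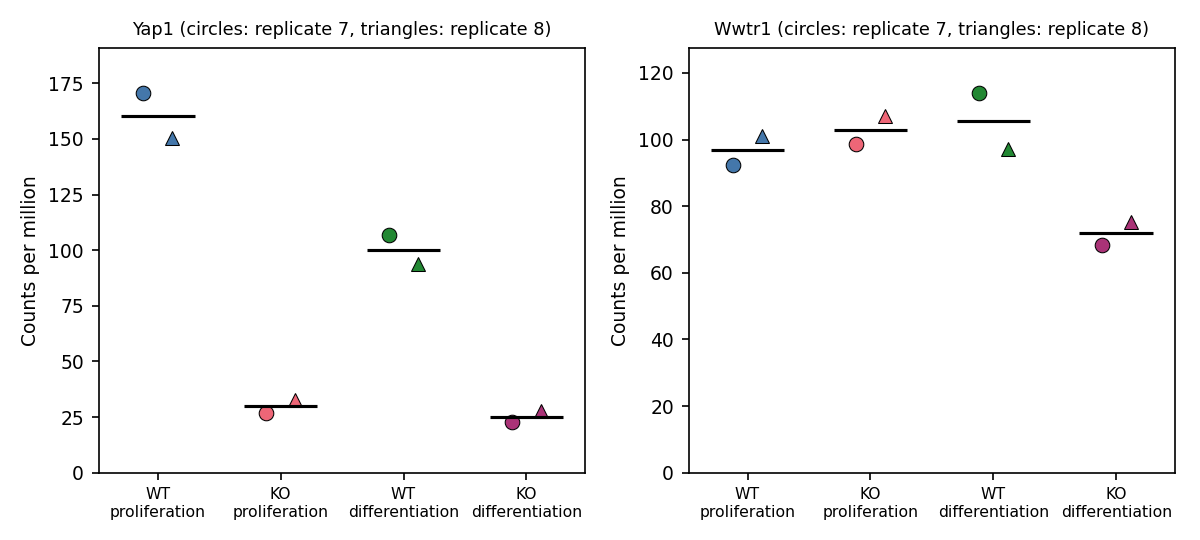
Yap1 (left) and Wwtr1 (right) in CPM on linear axes, 1 point per library (circles replicate 7, triangles replicate 8) with a bar at the mean of each group of 2. The KO libraries lie between 22.59 and 32.71 CPM for Yap1, below all WT libraries, whose lowest value is 93.69 CPM.

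The culture condition separated the libraries far more than the genotype. The first principal component of log2 CPM held 81.9% of the variance and parted proliferation from differentiation. The second held 10.7% and parted replicates numbered 7 from those numbered 8 in every group, so values within each number are given beside pooled values for the main genes below. Replicate libraries of 1 group correlated across genes with a Pearson r between 0.9646 (KO differentiation) and 0.9755 (WT proliferation), and genes are not independent replicates. They differed by more than counting noise, with a chi-square per degree of freedom from 33.1 in WT proliferation to 62.2 in KO differentiation.

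**Figure D2:**
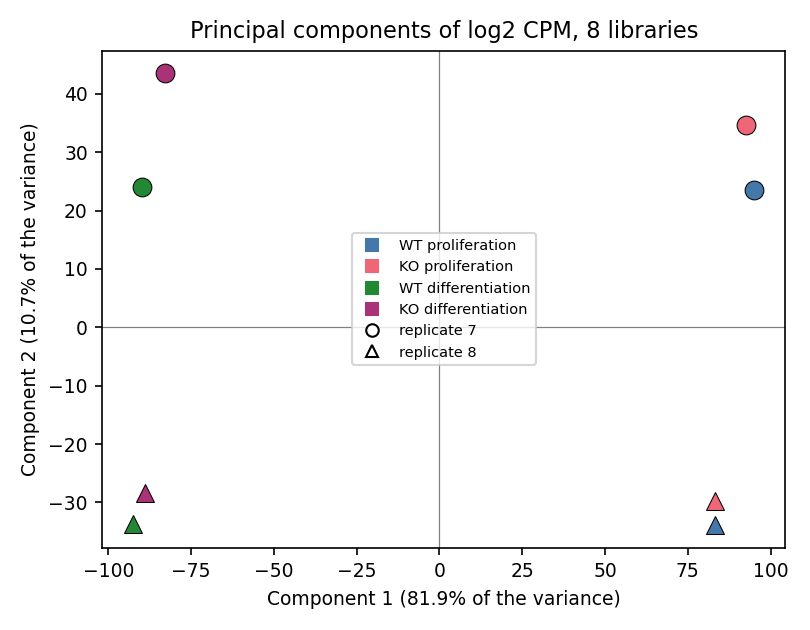
First and second principal components of log2 CPM (axis values are component scores), 1 point per library, coloured by group. Proliferation and differentiation separate along the first component (81.9% of the variance), replicates 7 and 8 along the second (10.7%).

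The comparison of KO with WT cells in proliferation asks how dividing cultures differ when YAP1 is depleted. Yap1 itself fell 5.369-fold, and no other gene passed the test in the main fit, while Bmp3 also passed with the replicate block. As groups, markers of ependymal cells (the ciliated lining of the central canal), cholesterol synthesis genes and mitosis genes were lower in KO, while markers of oligodendrocyte precursors, extracellular matrix genes and targets of EGF and FGF signalling through ERK were higher. These were list calls with the preset correlation of the camera test. None was kept with an estimated correlation (adjusted p from 0.307 to 0.754), and no member passed the gene test. The estimate for ependymal markers (0.00632) lay below the preset 0.01, so that loss does not show that these markers vary together. The established YAP/TAZ-TEAD target signature did not pass as a list, with 9 of its 19 tested members above 0 in log2 fold change and 10 below. Ccn1, a matricellular protein gene, stood at 5.148 ± 2.26 CPM (SD, n = 2) in WT and 3.042 ± 1.37 CPM (SD, n = 2) in KO. Tgfb2, a secreted growth factor gene, stood at 39.25 and 48.72 CPM (adjusted p = 1 for both, edgeR).

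For Yap1 the log2 fold change was -2.42 (SE 0.162, edgeR adjusted p = 0.0322), with -2.65 between the libraries numbered 7 and -2.2 between those numbered 8. This call was lost when any 1 of the 8 libraries was left out, although the log2 fold change kept a similar size (range given further below). The count of 0 genes higher and 1 lower stood beside 186 genes higher and 108 lower at an unadjusted p under 0.05, where chance alone would give about 652 in all. Same-numbered libraries deviated together (correlation of 0.784 between KO and WT proliferation), and the fit without a block counts this as spread. The low count therefore does not show that KO had no effect. Limma-voom called 0 genes higher and 1 lower, DESeq2 called 6 and 5, and the authors' deposited table holds 11 and 4 at a q-value under 0.05. Libraries of both genotypes did not overlap for 3952 tested genes (30.3%, where chance gives 33.3% for libraries that vary independently). These libraries did not, so a share below that value does not show a lack of difference.

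None of the 5 genes with the smallest p in the higher direction passed. Bmp3, a secreted ligand of the BMP family (gene ID 110075, chromosome 5, 98854415 to 98884053), stood at 10.45 ± 0.852 CPM (SD, n = 2) in WT and 34.63 ± 2.17 CPM (SD, n = 2) in KO. Its log2 fold change was 1.73 (SE 0.164, edgeR adjusted p = 0.148), with 1.86 and 1.57 within numbers 7 and 8. The authors' deposited table gives 1.73 with a q-value of 3.24e-11. Agt, which encodes angiotensinogen (gene ID 11606, chromosome 8, 124556587 to 124569706), stood at 11.72 ± 1.08 CPM (SD, n = 2) in WT and 24.31 ± 1.85 CPM (SD, n = 2) in KO (adjusted p = 0.295, edgeR). Lrp1, a large endocytic receptor, stood at 191.7 ± 12.8 and 337.9 ± 23.6 CPM (SD, n = 2; edgeR adjusted p = 0.373). Bhlhe41, a transcriptional repressor, stood at 5.278 and 10.28 CPM (edgeR adjusted p = 0.56). Kcnc1, a potassium channel gene, stood at 150.1 CPM in WT and 81.56 CPM in KO (edgeR adjusted p = 0.373), and Itga6, the gene of the laminin receptor subunit alpha 6, at 127.1 and 76.29 CPM (edgeR adjusted p = 1). This pair was chosen after the values were seen, because the authors' deposited table gives them q-values of 0.000135 and 0.000199. DESeq2 called Bmp3 (adjusted p = 2.62e-10), Agt (1.42e-09), Lrp1 (8.73e-10), Bhlhe41 (0.0118) and both of that pair.

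Of 24 listed ependymal markers 9 were tested. Of these, 7 had a negative and 2 a positive log2 fold change in proliferation, with a median of -0.78 (camera adjusted p = 0.000476 with the preset correlation; adjusted p = 0.307 with an estimated correlation). Within numbers 7 and 8 the median was -0.475 and -0.363, on log2 CPM with a prior count of 2, which shrinks folds of low counts (-0.694 over both numbers on that scale). Of the 9 markers, 2 had at most 3 counts in each group, Mia (-3.67) and Meig1 (0.03). They lie on opposite sides of the median, so leaving them out could not move it (-0.78). The median is the value of Dynlrb2, which lies well below 5 CPM. Markers above 5 CPM had log2 fold changes of -1.29 (Foxj1), -0.36 (Rfx2), -0.12 (Rfx3) and 0.2 (Hydin). Foxj1, the transcription factor that drives the formation of motile cilia, stood at 33.59 ± 12.1 CPM (SD, n = 2) in WT and 13.7 ± 3.69 CPM (SD, n = 2) in KO. The dynein light chain gene Dynlrb2 stood at 1.035 and 0.5985 CPM. The other tested markers above 5 CPM changed less, with Rfx2 at 6.58 and 5.136 CPM, Rfx3 at 70.75 and 65.32 CPM and Hydin at 17 and 19.5 CPM. Cholesterol synthesis genes had a median of -0.23 with 20 of 23 below 0 (camera adjusted p = 0.0017; adjusted p = 0.754 with an estimated correlation). Hmgcs1, which makes HMG-CoA, stood at 1297 ± 137 and 1019 ± 148 CPM (SD, n = 2). Mitosis genes had a median of -0.13 with 27 of 30 below 0 (camera adjusted p = 0.0253; adjusted p = 0.754 with an estimated correlation). The kinetochore gene Cenpf stood at 206.4 ± 25.1 and 176.2 ± 8.45 CPM (SD, n = 2).

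Oligodendrocyte precursor markers had a median of 0.24 with 11 of 16 above 0 (camera adjusted p = 0.00524; adjusted p = 0.733 with an estimated correlation). Cspg4, the proteoglycan NG2, stood at 103.7 ± 6.64 CPM (SD, n = 2) in WT and 192.9 ± 2.23 CPM (SD, n = 2) in KO. The adhesion molecule gene Cntn1 stood at 33.59 ± 9.31 and 60.88 ± 12.4 CPM (SD, n = 2). Extracellular matrix genes had a median of 0.27 with 22 of 29 above 0 (camera adjusted p = 0.0311; adjusted p = 0.733 with an estimated correlation). The laminin chain gene Lama5 stood at 339 and 408.4 CPM. ERK targets had a median of 0.21 with 17 of 19 above 0 (camera adjusted p = 0.0311; adjusted p = 0.733 with an estimated correlation). The feedback inhibitor gene Spry1 stood at 156.9 ± 17.9 and 196 ± 17.8 CPM (SD, n = 2) and the phosphatase gene Dusp5 at 10.32 and 15.72 CPM.

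No member of these 6 lists passed the gene test, and adjusted over the list alone the calls were Agt in the astrocyte markers (higher) and Yap1 in the Hippo pathway components (lower). The other 19 lists tested did not pass, the YAP/TAZ-TEAD signature included (camera adjusted p = 0.883), and the interferon list had a median and a test direction above 0 with a mean below 0 (-0.13). The ependymal call was kept with every library left out. Without KO proliferation replicate 8 the camera adjusted p was 0.2 for oligodendrocyte precursor markers, 0.719 for extracellular matrix, 0.639 for ERK targets and 0.719 for cholesterol synthesis, whose direction turned upward (medians of 0.22, -0.10, 0.08 and 0.00). Without WT proliferation replicate 7 these lists also lost their calls, with medians of 0.21, 0.23, 0.14 and 0.01. In the same order, their medians were 0.29, 0.30, 0.23 and -0.46 without KO proliferation replicate 7. They were 0.45, 0.25, 0.20 and -0.39 without WT proliferation replicate 8. The mitosis call was lost without KO proliferation replicate 7 (adjusted p = 0.298, median -0.06) or WT proliferation replicate 8 (0.165, median -0.10).

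The comparison of KO with WT cells in differentiation asks the same of cultures that have left the cycle. No gene passed the test in the main fit, Yap1 included, while Cd109, Foxj1 and Yap1 were called lower with the replicate block. As groups, the remaining transcripts of mitosis genes, ependymal markers, interferon response genes, Hox genes, actin cytoskeleton genes, Hippo pathway components (Yap1 itself included) and BMP and TGF-beta targets were lower in KO, and cholesterol synthesis genes were higher. None of these list calls was kept with an estimated correlation (adjusted p from 0.395 to 0.735), and all but the mitosis call were lost without KO differentiation replicate 8, where the medians of these lists kept their signs. Yap1 had a log2 fold change of -1.99 (SE 0.161, edgeR adjusted p = 0.106), with -2.24 and -1.75 within numbers 7 and 8, and the authors' deposited table gives -1.99 with a q-value of 1.69e-16. Wwtr1 had a log2 fold change of -0.56 (SE 0.12, edgeR adjusted p = 0.909), with -0.74 and -0.37 within the numbers, and a q-value of 0.557 in the authors' deposited table.

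The count of 0 genes in either direction (edgeR) stood beside 244 genes higher and 378 lower at an unadjusted p under 0.05, where chance would give about 652 in all. Same-numbered libraries deviated together here as well (correlation of 0.703 between KO and WT differentiation), and the fit without a block counts this as spread. Limma-voom also called 0 and 0, DESeq2 called 4 genes higher and 34 lower, and the authors' deposited table holds 1 gene higher and 23 lower. Without the filter on low counts, Yap1 passed in edgeR (adjusted p = 0.0389). Libraries did not overlap for 4109 tested genes (31.5%, where chance gives 33.3% for libraries that vary independently, unlike these). In simulated data with 2 libraries per group, the edgeR test recovered 71.2% of genes changed 4-fold and 34.3% of genes changed 2-fold in this comparison.

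None of the 5 genes with the smallest p in either direction passed (edgeR adjusted p = 0.106 for Yap1 and 0.909 for each of the others). In the higher direction, Bmp3 stood at 4.12 CPM in WT and 8.295 CPM in KO, with a log2 fold change of 0.99 within both numbers. Rps21, a protein of the small ribosomal subunit (gene ID 66481, chromosome 2, 180257379 to 180258444), stood at 82.43 ± 6.52 and 147.5 ± 23.1 CPM (SD, n = 2), a count that may include reads shared with processed copies of the gene. The tyrosyl-tRNA synthetase gene Yars stood at 74.07 and 104.1 CPM, the sorting nexin gene Snx25 at 60.59 and 80.99 CPM, and Nin, which encodes the centrosomal protein ninein, at 23.64 and 36.74 CPM. In the lower direction, Ifitm3, an interferon-induced membrane protein (gene ID 66141, chromosome 7, 141009590 to 141010744), stood at 140.5 ± 22.4 CPM (SD, n = 2) in WT and 67.7 ± 0.424 CPM (SD, n = 2) in KO. The tetraspanin gene Tspan4 (gene ID 64540) stood at 21.51 and 10.74 CPM, Piezo1, a mechanically gated ion channel, at 12.83 and 7.458 CPM, and Net1, an exchange factor for small GTPases, at 7.006 and 3.44 CPM. Gfap, the intermediate filament of astrocytes, was at 2711 ± 293 CPM (SD, n = 2) in WT and 864 ± 587 CPM (SD, n = 2) in KO (edgeR adjusted p = 0.934). Its log2 fold changes were -2.70 and -0.97 within numbers 7 and 8. DESeq2 called Yap1, Bmp3, Yars, Rps21, Piezo1, Tspan4, Ifitm3, Net1, Wwtr1 (adjusted p = 0.0499), Cnn3, Vcl and Gfap (adjusted p = 0.0322).

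Mitosis genes, nearly silent in differentiation, had a median log2 fold change of -0.57 with 25 of 30 below 0 (camera adjusted p = 1.04e-05; adjusted p = 0.445 with an estimated correlation), with -0.365 and -0.384 within numbers 7 and 8. Mki67, the proliferation marker Ki-67, stood at 1.419 CPM in WT and 0.4903 CPM in KO, and Prc1, an organiser of the mitotic spindle midzone, at 2.883 and 1.844 CPM. The list summed to 38.77 and 43.66 CPM in the WT libraries and to 28 and 36.99 CPM in the KO libraries, against sums from 4732 to 5375 CPM in proliferation. Ependymal markers had a median of -0.69 with 6 of 9 below 0 (camera adjusted p = 0.00559; adjusted p = 0.395 with an estimated correlation), with -1.01 and -0.443 within the numbers. Foxj1 stood at 57.31 ± 8.52 CPM (SD, n = 2) in WT and 23.06 ± 7.74 CPM (SD, n = 2) in KO, and Rfx2, a transcription factor of ciliated cells, at 19.26 and 11.93 CPM. Rfx3, among the markers above 0, stood at 93.53 and 117.8 CPM. The authors' deposited table gives Foxj1 a log2 fold change of -1.31 with a q-value of 0.0175.

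Cholesterol synthesis genes had a median of 0.25 with 21 of 23 above 0 (camera adjusted p = 0.00041; adjusted p = 0.735 with an estimated correlation). Fdps, which makes farnesyl diphosphate, stood at 152 ± 27.7 and 239.7 ± 7.76 CPM (SD, n = 2). Interferon response genes had a median of -0.21 with 12 of 14 below 0 (camera adjusted p = 0.00559; adjusted p = 0.395 with an estimated correlation), Ifitm3 and the chemokine gene Cxcl10 (1.052 and 0.1406 CPM) among them. Hox genes, which set position along the body axis, had a median of -0.2 with 24 of 27 below 0 (camera adjusted p = 0.00939; adjusted p = 0.666 with an estimated correlation). Hoxa9 stood at 91.33 and 66.15 CPM, but the median of the list was -0.41 within number 7 and 0.01 within number 8. BMP and TGF-beta targets had a median of -0.39 with 10 of 13 below 0 (camera adjusted p = 0.0442; adjusted p = 0.53 with an estimated correlation), with -0.82 within number 7 and 0.00 within number 8. Smad9, a transducer of BMP signals, stood at 23.96 ± 0.553 and 14.98 ± 2.59 CPM (SD, n = 2).

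Actin cytoskeleton genes and targets of the transcription factor SRF had a median of -0.12 with 12 of 18 below 0 (camera adjusted p = 0.0255; adjusted p = 0.445 with an estimated correlation). The actin-binding protein gene Cnn3 stood at 812 ± 70.4 CPM (SD, n = 2) in WT and 564.7 ± 15.4 CPM (SD, n = 2) in KO. Vcl, the focal adhesion protein vinculin, stood at 210.1 ± 4 and 147.8 ± 12.9 CPM (SD, n = 2). Hippo pathway components had a median of -0.08 with 17 of 26 below 0 (camera adjusted p = 0.0255; adjusted p = 0.445 with an estimated correlation). The targeted Yap1 (log2 fold change -1.99) counts toward this test, and the list was not tested without it. The YAP/TAZ-TEAD signature had 6 members above 0 and 13 below with a median of -0.18 and did not pass (camera adjusted p = 0.291). Tgfb2 stood at 198.3 ± 43.6 and 126.3 ± 19 CPM (SD, n = 2), and Arhgef17, an exchange factor for small GTPases, at 28.41 and 13.1 CPM.

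Adjusted over the list alone, Ifitm3, Cnn3, Vcl, Yap1, Wwtr1 and the Schwann cell marker Drp2 were called lower, and no list member was called over all genes. The other 17 lists did not pass. The p53 targets had a median above 0 (its sign flips with the scaling) with a mean and test below 0. The Schwann cell markers had a median and mean above 0 with a test below 0, and the hypoxia list a median and test above 0 with a mean below 0. The mitosis call was kept with every library left out, and it was the only one kept without KO differentiation replicate 8. There the camera adjusted p was 0.569 for Hippo components, 0.176 for ependymal markers, 0.3 for actin genes, 0.225 for interferon genes, 0.211 for cholesterol synthesis, 0.176 for BMP targets and 0.176 for Hox genes. The medians there were -0.98 for ependymal markers, -0.36 for interferon genes, -0.27 for Hox genes, -0.39 for BMP targets and -0.09 for Hippo components, none nearer 0 than with all libraries. They were -0.10 for actin genes and 0.21 for cholesterol synthesis, slightly nearer 0. The mitosis median was -0.91 without this library and -0.24 without KO differentiation replicate 7, where the ependymal median was -0.45. Without WT differentiation replicate 7 it was 0.215 for Hippo components, 0.136 for cholesterol synthesis, 0.923 for BMP targets and 0.969 for Hox genes, whose direction turned upward (medians of -0.09, 0.15, 0.02 and 0.02). Actin genes (0.433, median -0.09) and interferon genes (0.0909, median -0.12) lost the call without WT differentiation replicate 8, and BMP targets (0.38, median -0.34) without KO differentiation replicate 7.

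**Figure D3:**
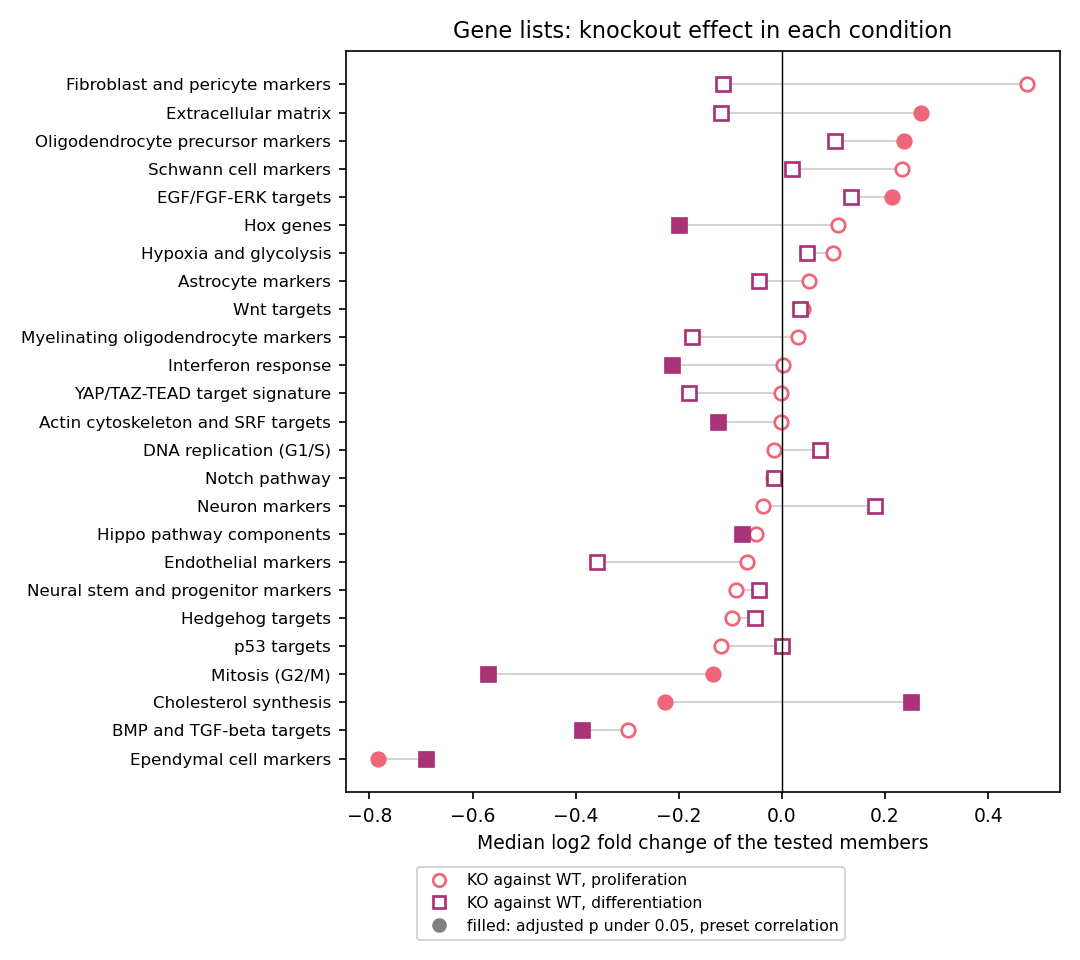
Median log2 fold change, KO over WT, of the tested members of each of 25 gene lists, in proliferation (circles) and in differentiation (squares), filled where the camera adjusted p with the preset correlation was under 0.05. Cholesterol synthesis lies at -0.23 in proliferation and 0.25 in differentiation, and ependymal markers at -0.78 and -0.69, and none of these calls was kept with an estimated correlation.

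Differentiation against proliferation in WT cells shows how cultures after 5 days of differentiation differed from cultures after 7 days of growth. Genes of DNA replication and mitosis fell, with all 30 tested members of each list lower. Astrocyte genes rose, 19 of 21 of them, led by Gfap (gene ID 14580, chromosome 11, 102887336 to 102897200), which went from 0.4246 ± 0.151 CPM (SD, n = 2) to 2711 ± 293 CPM (SD, n = 2). Targets of EGF and FGF signalling fell, 15 of 19. Neuron and interferon response lists were called higher with the preset correlation (adjusted p = 0.775 and 0.31 with an estimated correlation), with 6 of 18 and 5 of 14 members higher. Of these 6 lists, DNA replication alone kept its call with an estimated correlation, while fry, which does not compare a list with other genes, called all 6. In all, edgeR called 3520 genes higher and 3698 lower, and the libraries of both conditions did not overlap for 10594 tested genes (81.2%, where chance gives 33.3%). The authors' deposited table holds 3365 and 3443, and limma-voom called 3531 and 3722.

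Among the genes with the largest rises, Gfap had a log2 fold change of 12.62 (SE 0.754, edgeR adjusted p = 6.56e-05), with 12.7 and 11.9 within numbers 7 and 8. Genes with no count in WT proliferation were compared with a floor of 3 counts over the group. Fmod, a collagen-binding proteoglycan, was at least 213-fold higher (edgeR adjusted p = 0.00346), the ectonucleotidase gene Entpd2 at least 187-fold (0.000972), and the urea transporter gene Slc14a1 at least 149-fold (0.00408). The copine gene Cpne6 was higher at least 119-fold (adjusted p = 0.00138) and Bbox1, an enzyme of carnitine synthesis, at least 73.4-fold (0.00166). Gpr149, an orphan receptor, was at least 136-fold higher (edgeR adjusted p = 0.0202), a call lost without WT proliferation replicate 7 (adjusted p = 0.0609) or 8 (0.0583) and with limma-voom (0.0545). Fxyd1, a regulator of the sodium pump, had 1 count in WT proliferation and a ratio of 1440 (95% counting interval 258 to 57000; edgeR adjusted p = 0.000246).

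Among the genes with the largest falls, 6 act in DNA synthesis or cell division. Mki67 (gene ID 17345, chromosome 7, 135689784 to 135716450) went from 600.2 ± 77.4 to 1.419 ± 0.42 CPM (SD, n = 2), a log2 fold change of -8.71 (SE 0.324, edgeR adjusted p = 1.04e-05), with -8.79 and -8.49 within the numbers. Tk1, the thymidine kinase of S phase, went from 114.7 ± 11.8 to 0.1646 CPM (log2 fold change -9.39, edgeR adjusted p = 4.76e-06), and Depdc1a, a mitotic regulator, from 53.5 to 0.1085 CPM (-8.85, adjusted p = 1.44e-05). On the log2 scale, the mitotic kinase gene Aurkb fell by 8.80 (edgeR adjusted p = 6.11e-05), cyclin B1 (Ccnb1) fell by 8.61 (5.85e-05) and the PCNA-binding factor gene Pclaf fell by 8.56 (6.12e-05). Spp1, which encodes osteopontin, had 1 count in WT differentiation and was lower by a ratio of 535 (95% counting interval 95.6 to 21200; edgeR adjusted p = 0.000165). The serotonin receptor gene Htr1b was at least 103-fold lower (edgeR adjusted p = 0.0195), a call lost without WT differentiation replicate 7 (adjusted p = 0.0681) or 8 (0.0666) or WT proliferation replicate 7 (0.0516). It was also lost with limma-voom (adjusted p = 0.0941 for Htr1b, 0.1 with quality weights).

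The mitosis list had a median of -7.02 (camera adjusted p = 3e-18; adjusted p = 0.159 with an estimated correlation), with Prc1 going from 256.3 to 2.883 CPM (edgeR adjusted p = 4.76e-06). The DNA replication list had a median of -4.29 and was the only list kept with an estimated correlation (camera adjusted p = 4.19e-18; adjusted p = 0.0131 with an estimated correlation). Mcm6, a subunit of the replicative helicase, went from 275.5 ± 0.542 to 22.45 ± 1.18 CPM (SD, n = 2; edgeR adjusted p = 5.34e-06). Astrocyte markers had a median of 3.61 (camera adjusted p = 1.4e-07; adjusted p = 0.0945 with an estimated correlation). Agt went from 11.72 ± 1.08 to 1030 ± 25.7 CPM (SD, n = 2; edgeR adjusted p = 4.76e-06). The protease inhibitor gene Cst3 went from 132.4 to 2680 ± 282 CPM (SD, n = 2; edgeR adjusted p = 1.68e-05) and the GABA transporter gene Slc6a11 from 106.9 to 1899 ± 304 CPM (SD, n = 2).

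ERK targets had a median of -1.54 with 15 lower, 2 higher and 2 not passing (camera adjusted p = 0.0023; adjusted p = 0.251 with an estimated correlation). Cyclin D1 (Ccnd1) went from 2572 ± 102 to 30.49 ± 8.76 CPM (SD, n = 2; edgeR adjusted p = 0.000253), Spry4 from 329.1 to 4.373 CPM (0.000176) and Spry1 from 156.9 to 7.054 CPM (4.04e-05). The members that rose, Fos, an immediate early gene (8.12 to 88.2 CPM, edgeR adjusted p = 0.00527), and Il17rd, a feedback inhibitor (7.06 to 35.8 CPM, adjusted p = 0.000668), were chosen after the values were seen. Neuron markers had a median of 1.74 with 6 higher, 1 lower and 11 not passing (camera adjusted p = 0.0344; adjusted p = 0.775 with an estimated correlation). Nsg2, a neuronal vesicle protein gene, went from 35.2 ± 5.6 to 269.4 ± 36.4 CPM (SD, n = 2; edgeR adjusted p = 6.11e-05). The growth cone gene Gap43 fell from 186.8 to 36.4 ± 12.8 CPM (SD, n = 2; adjusted p = 0.00152). Interferon response genes had a median of 0.77 with 5 of 14 higher (camera adjusted p = 0.0344; adjusted p = 0.31 with an estimated correlation). Ifit3, an interferon-induced gene, rose from 0.2126 to 10.62 CPM (edgeR adjusted p = 0.00306). Ifit3 resembles Ifit3b in sequence, so reads could be shared between them. The neuron call was lost without WT differentiation replicate 8 (camera adjusted p = 0.0569) or WT proliferation replicate 7 (0.0519), and the interferon call without WT differentiation replicate 8 (0.0665). Counts adjusted over the list alone were the same as over all genes for these 6 lists.

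The other 19 lists did not pass as lists in WT. Many of their members did pass, but so did 55.3% of all tested genes. Among neural stem and progenitor markers 7 rose and 5 fell of 21 (camera adjusted p = 0.849). Nes, the intermediate filament of progenitors, fell from 1452 ± 151 to 188.5 ± 23.7 CPM (SD, n = 2; edgeR adjusted p = 6.64e-05). Sox2, a transcription factor of stem cells, rose from 172.2 ± 8.57 to 617.3 ± 64.1 CPM (SD, n = 2; adjusted p = 0.000111). Notch pathway genes had 10 higher and 2 lower of 18 (camera adjusted p = 0.0786), with the effector gene Hes5 rising from 4.088 to 56.47 ± 4.33 CPM (SD, n = 2; edgeR adjusted p = 0.0015). Oligodendrocyte precursor markers had 7 higher and 3 lower of 16 (camera adjusted p = 0.407). The growth factor receptor gene Pdgfra rose from 5.095 ± 1.81 to 96.29 ± 19.7 CPM (SD, n = 2; edgeR adjusted p = 9.55e-05). Olig2, a transcription factor of the lineage, fell from 1209 ± 75.8 to 494.8 ± 0.942 CPM (SD, n = 2; adjusted p = 0.000312). Myelinating oligodendrocyte markers had 6 higher and 2 lower of 15 (camera adjusted p = 0.163).

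The YAP/TAZ-TEAD signature had 7 higher and 1 lower of 19 (camera adjusted p = 0.318). The receptor kinase gene Axl rose from 23.48 ± 2.57 to 191 ± 30.6 CPM (SD, n = 2; edgeR adjusted p = 3.71e-05). Igfbp3, an IGF-binding protein gene, fell from 640.7 ± 106 to 18.06 ± 5.55 CPM (SD, n = 2; adjusted p = 7.17e-05). BMP and TGF-beta targets had 8 higher and 1 lower of 13 (camera adjusted p = 0.213), with Id2, an inhibitor of differentiation factors, rising from 23.58 to 273.1 ± 91.3 CPM (SD, n = 2; edgeR adjusted p = 0.000103). Extracellular matrix genes had 4 higher and 8 lower of 29 (camera adjusted p = 0.318), with Lama5 falling from 339 to 26.24 CPM (edgeR adjusted p = 5.96e-06). Actin genes had 2 higher and 9 lower of 18 (camera adjusted p = 0.163), the hypoxia and glycolysis list 0 and 6 of 22 (0.318), ependymal markers 4 and 1 of 9 (0.555), and cholesterol synthesis 2 and 5 of 23 (0.857). Hippo components had 5 higher and 8 lower of 26 (camera adjusted p = 0.94), and endothelial markers, nearly absent at 1.019 to 10.64 CPM in sum, 0 and 4 of 5 (0.0786). Higher and lower members numbered 5 and 3 for p53 targets, 4 and 3 for fibroblast and pericyte markers and 2 and 2 for Schwann cell markers. They numbered 2 and 3 for Hox genes, 3 and 3 for Hedgehog targets and 1 and 3 for Wnt targets. The test opposed both median and mean for the Hippo (a median whose sign flips with the scaling), p53 and Schwann lists, and the median and mean opposed each other for the fibroblast and Hox lists. Microglia and macrophage markers had 2 tested members and sex-linked genes 0, too few for the list test.

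Yap1 itself was lower in differentiation, from 160.4 ± 14.1 to 100.3 ± 9.29 CPM (SD, n = 2; log2 fold change -0.68, SE 0.154, edgeR adjusted p = 0.0097). This call was lost without WT differentiation replicate 8 (adjusted p = 0.0619) or WT proliferation replicate 7 (adjusted p = 0.0578), and the authors' deposited table gives -0.67 with a q-value of 0.000343. Wwtr1 had a log2 fold change of 0.13 (edgeR adjusted p = 0.401).

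Differentiation against proliferation in KO cells asks whether YAP1-depleted cultures make the same transition. The same division genes fell and astrocyte genes rose, with 30 of 30 mitosis and 30 of 30 DNA replication genes lower and 19 of 21 astrocyte markers higher. Mki67 went from 577 ± 40.6 to 0.4903 ± 0.291 CPM (SD, n = 2) and Gfap from 0.3807 to 864 ± 587 CPM (SD, n = 2). EdgeR called 3281 genes higher and 3480 lower (51.8% of those tested), limma-voom 3232 and 3488, and the authors' deposited table holds 2750 and 2870, and libraries did not overlap for 9903 tested genes (75.9%, where chance gives 33.3%). Both genotypes shared 2880 higher genes, where independent lists would share 885, and 3104 lower genes, where independent lists would share 986. The log2 fold changes of both genotypes correlated across genes with r = 0.951, and genes are not independent replicates.

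Of the largest rises, Gfap had a log2 fold change of 11.12 (SE 0.731, edgeR adjusted p = 0.000102), with 9.84 and 11.4 within numbers 7 and 8. The water channel gene Aqp4 rose from 1.655 to 767.8 ± 772 CPM (SD, n = 2; edgeR adjusted p = 0.00219). Gpr17, a receptor of maturing oligodendrocyte precursors, rose from 0.8124 to 406.2 ± 399 CPM (SD, n = 2; adjusted p = 0.00641). Both had an SD near the mean, and the Gpr17 call was lost with limma-voom (adjusted p = 0.0875, or 0.0631 with quality weights). Against the floor, the interferon-induced gene Ifit3b was at least 165-fold higher (edgeR adjusted p = 0.000446), the RNA-binding protein gene Khdrbs2 at least 64.2-fold (0.00311) and Gpr149 at least 91.6-fold (0.0261). The Gpr149 call was lost without KO differentiation replicate 8 (adjusted p = 0.0639), KO proliferation replicate 7 (0.065) or KO proliferation replicate 8 (0.0624), and with limma-voom (0.0766, or 0.0618 with quality weights). Shisa9, an auxiliary subunit of AMPA receptors, had 3 counts in KO proliferation and a ratio of 729 (95% counting interval 249 to 3540; edgeR adjusted p = 6.48e-06). Lgi4, a secreted protein of myelination, had 2 counts and a ratio of 581 (161 to 4810; adjusted p = 0.00175), a call lost with limma-voom (adjusted p = 0.0727).

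Of the largest falls, Mki67 had a log2 fold change of -10.17 (edgeR adjusted p = 9.7e-06) and Pclaf of -9.86 (adjusted p = 5.4e-05). The DNA glycosylase gene Neil3 was at least 225-fold lower (edgeR adjusted p = 2.08e-05) and the kinetochore gene Ska1 at least 149-fold (4.98e-05). Depdc1a was lower by a ratio of 1710 with 1 count in KO differentiation (95% counting interval 307 to 67800; edgeR adjusted p = 1.37e-05). The mitotic kinase gene Pbk was lower by a ratio of 1110 with 3 counts (379 to 5380; adjusted p = 5.04e-05). Klri1, a receptor gene of natural killer cells, was at least 77.2-fold lower (edgeR adjusted p = 0.000649) and Raet1d, a stress ligand gene of the NKG2D receptor, at least 75.3-fold (0.000505), where reads could be shared with close relatives in either family.

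As lists, mitosis had a median of -7.48 (camera adjusted p = 8.2e-20; adjusted p = 0.138 with an estimated correlation) and DNA replication of -4.24 (camera adjusted p = 5.01e-19; adjusted p = 0.0118 with an estimated correlation). Astrocyte markers had a median of 3.83 (camera adjusted p = 6.82e-08; adjusted p = 0.0876 with an estimated correlation). Mcm6 went from 276.8 ± 9.08 to 23.43 ± 0.66 CPM (SD, n = 2; edgeR adjusted p = 5.76e-06). Agt went from 24.31 ± 1.85 to 905.2 ± 43.8 CPM (SD, n = 2; adjusted p = 5.71e-06) and Cst3 from 149.7 to 3666 ± 399 CPM (SD, n = 2; adjusted p = 1.37e-05). ERK targets had a median of -1.45 with 16 lower, 2 higher and 1 not passing (camera adjusted p = 0.000697; adjusted p = 0.197 with an estimated correlation), and 3 higher adjusted over the list alone. Ccnd1 went from 2587 ± 128 to 29.95 ± 20.7 CPM (SD, n = 2; edgeR adjusted p = 0.000321). Neuron markers had a median of 1.92 with 9 higher, 1 lower and 8 not passing (camera adjusted p = 0.00961; adjusted p = 0.672 with an estimated correlation). Nsg2 went from 39.88 to 255.4 ± 8.92 CPM (SD, n = 2; edgeR adjusted p = 8.88e-05) and Gap43 from 189.2 to 38.44 CPM (0.00189).

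The other 20 lists did not pass in KO, the interferon list with 3 of 14 higher among them (camera adjusted p = 0.334). The test opposed the median and mean of the Schwann list, and the mean of the p53 list lay below 0 with its test and its median above, a median whose sign flips with the scaling. Nes fell from 1182 ± 123 to 195.1 ± 32.4 CPM (SD, n = 2; edgeR adjusted p = 0.000109) and Sox2 rose from 180.7 to 538.3 ± 71.3 CPM (SD, n = 2; adjusted p = 0.00023). Pdgfra rose from 7.015 to 132.4 ± 17.9 CPM (SD, n = 2; edgeR adjusted p = 0.000105) and Olig2 fell from 1409 to 613 ± 78.1 CPM (SD, n = 2; adjusted p = 0.000504). In the YAP/TAZ-TEAD signature 6 rose and 1 fell of 19 (camera adjusted p = 0.336), Axl from 27.33 to 144.1 CPM (edgeR adjusted p = 8.83e-05) and Igfbp3 from 628.5 to 21.03 CPM (8.96e-05). Yap1 had a log2 fold change of -0.25 (edgeR adjusted p = 0.231). Wwtr1 fell by 0.52 on the log2 scale (SE 0.12, edgeR adjusted p = 0.0116), a call lost without KO differentiation replicate 7 (adjusted p = 0.0506) or KO proliferation replicate 8 (adjusted p = 0.0665).

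**Figure D4:**
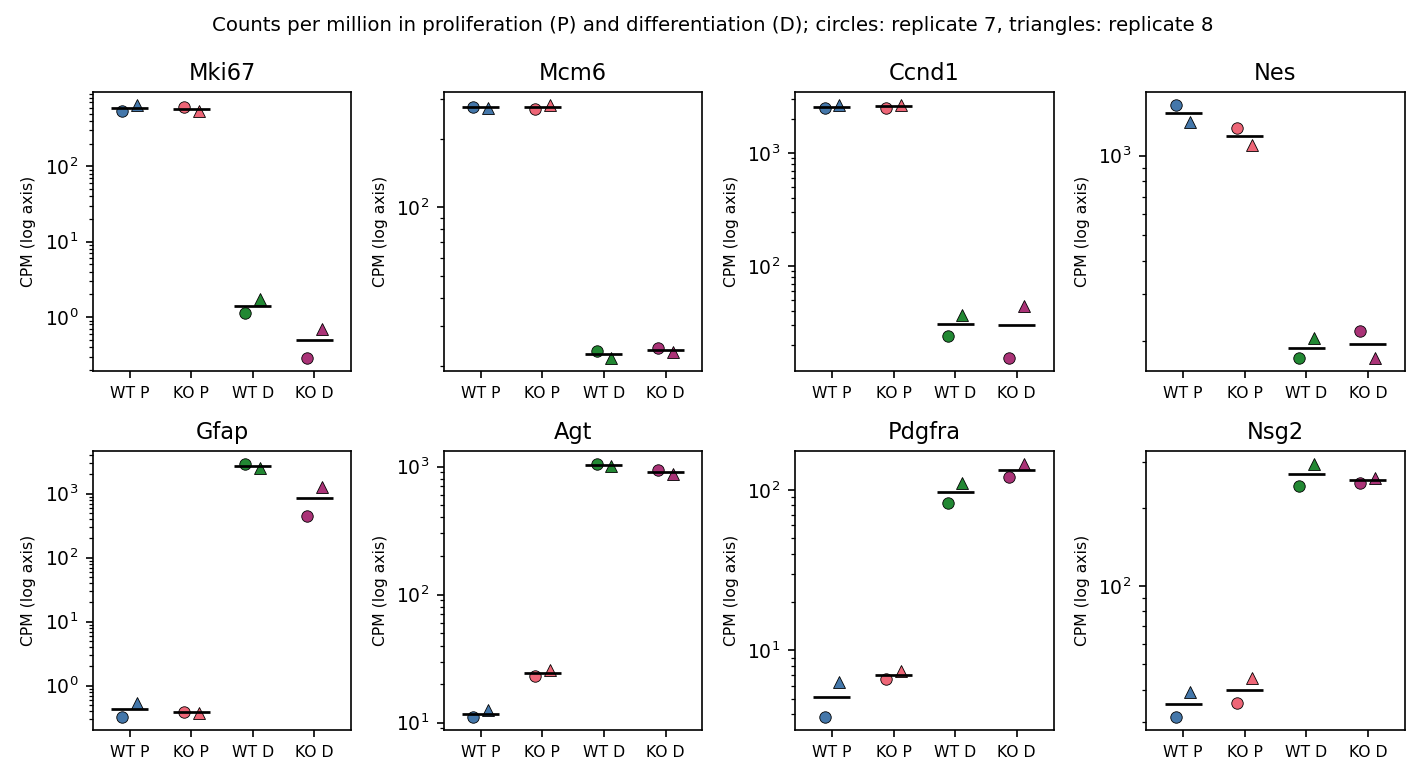
CPM on log axes for 8 genes, 1 point per library (circles replicate 7, triangles replicate 8), with a bar at the mean of each group of 2 libraries. Mki67, Mcm6, Ccnd1 and Nes are lower and Gfap, Agt, Pdgfra and Nsg2 higher in differentiation in both genotypes, and the KO differentiation libraries spread widely for Gfap (864 ± 587 CPM, SD, n = 2).

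The difference between both KO effects (differentiation minus proliferation) tests whether the difference between KO and WT depended on the condition. No gene passed in either direction with edgeR (smallest adjusted p = 0.981), where 209 genes were higher and 349 lower at an unadjusted p under 0.05. Limma-voom called 0 and 0, and DESeq2 called 3 genes higher, Rpl29 and Yars among them, and 9 lower. The log2 fold changes of KO over WT in both conditions correlated across genes with r = 0.0869, and genes are not independent replicates. Agt, chosen after its values were seen as the gene with the smallest p in the lower direction, stood at 11.72 and 24.31 CPM in proliferation and 1030 and 905.2 CPM in differentiation (WT and KO), a difference of KO effects of -1.24. For Yap1 the difference was 0.43 (adjusted p = 0.981 for both, edgeR).

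Among lists tested on this difference, an addition made after the data were seen, cholesterol synthesis genes had 22 of 23 members above 0 with a median of 0.46 (camera adjusted p = 5.46e-06; adjusted p = 0.767 with an estimated correlation). Interferon response genes had 11 of 14 below 0 with a median of -0.58, and Hox genes 25 of 27 below 0 with a median of -0.36 (camera adjusted p = 0.0098 for each; adjusted p = 0.767 with an estimated correlation for each). A simulated list of 20 genes raised 1.5-fold in KO differentiation also failed with an estimated correlation on this difference (camera adjusted p = 0.471). A call lost that way therefore cannot decide here whether a list shifted. The other 22 lists did not pass, and among them median, mean and test differed in sign for the Schwann, Notch, Hedgehog, Wnt, ependymal and BMP lists. Adjusted over the list alone, 1 member each of the extracellular matrix, astrocyte and ERK lists was lower. The cholesterol call was kept with every library left out (highest camera adjusted p = 0.0465). The interferon call was lost without KO differentiation replicate 8 (0.083), WT differentiation replicate 8 (0.155) or WT proliferation replicate 7 (0.114), and the Hox call without KO differentiation replicate 8 (0.0539), WT differentiation replicate 7 (0.555) or WT proliferation replicate 7 (0.083).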

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

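The tests of gene lists on the difference between KO effects, the ribosome gene set, and the tests of shared fluctuation and of single libraries for cholesterol synthesis, and the values within replicate numbers, were chosen only after results had been seen, the other tests before.

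Cytosolic ribosome genes, taken from a search over 1891 Gene Ontology terms, had 76 of 80 members below 0 in KO in proliferation (median log2 fold change -0.16) and 70 of 80 above 0 in differentiation (median 0.21; camera adjusted p = 4.98e-10 and 3.48e-08; adjusted p = 0.819 and 0.871 with an estimated correlation). A difference between both KO effects marked them, with a median of 0.32 (camera adjusted p = 6.23e-16; adjusted p = 0.682 with an estimated correlation). Genes matched in transcript length and GC content had a median difference of 0.0503 (against 0.331 for the 79 members with a length), which argues against such a bias. The median difference was lowest without WT proliferation replicate 7, at 0.226 (95% bootstrap interval over genes 0.173 to 0.286). This lies above the limit of 0.161 set beforehand and argues against a single library as the source of the whole difference. The differentiation effect alone (0.21) exceeds that limit, so the test cannot decide for the proliferation effect. There WT replicate 7 stood at a median of 0.599, against 0.404 in WT replicate 8 and 0.34 and 0.333 in KO (log2 CPM relative to the mean of each gene). A fluctuation shared by these genes remains open, because the WT proliferation replicates differed by a median of 0.205, more than the smaller KO effect of 0.156. The KO effects nevertheless kept their signs within numbers 7 and 8 (-0.256 and -0.0577 in proliferation, 0.254 and 0.0935 in differentiation). A biological effect of YAP1, of the virus or of the allele that depends on the culture condition is also open and was not tested.

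Cholesterol synthesis genes were marked by the same difference (camera adjusted p = 5.46e-06; adjusted p = 0.767 with an estimated correlation), lower in KO in proliferation and higher in differentiation, with a median difference of 0.456. Genes matched in length and GC content had a median difference of -0.0164 (95% of matched sets between -0.185 and 0.116), which argues against such a bias. A shared fluctuation stays open, since the KO proliferation replicates differed by a median of 0.459, more than the smaller KO effect of 0.226, but the WT replicates differed alike (0.413), and the KO effects kept their signs within numbers 7 and 8 (-0.197 and -0.259 in proliferation, 0.351 and 0.203 in differentiation), so it would have to differ between same-numbered libraries, and no label pairs these. Without KO proliferation replicate 8 the median difference was 0.229 (95% bootstrap interval over genes 0.184 to 0.44) against a limit of 0.228, and without WT proliferation replicate 7 it was 0.27. Leaving out either library also unbalances the numbers, between which both genotypes shifted alike. The test therefore cannot tell the weight of 1 library from that shared shift or from a change in the group. A biological effect of YAP1, of the virus or of the allele on the pathway stays open as well and was not tested.

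Ependymal markers (9 of 24 listed were tested) were called lower in KO in both conditions with the preset correlation, by medians of -0.78 in proliferation (-0.475 and -0.363 within numbers 7 and 8) and -0.69 in differentiation (-1.01 and -0.443), but not with an estimated correlation (adjusted p = 0.307 and 0.395). No member passed edgeR without a block, although the authors' deposited table gives Foxj1 -1.31 in differentiation with a q-value of 0.0175, and without KO differentiation replicate 8 the list lost its differentiation call (adjusted p = 0.176) while its median moved further from 0 (-0.98, against -0.45 without replicate 7). Other motile cilium genes (143 of them) had a median KO effect of -0.012 in proliferation (95% bootstrap interval over genes -0.0491 to 0.0205) and -0.105 in differentiation (-0.142 to -0.00805). The bound written beforehand would have excluded a loss of ciliated cells, but it was wrong, because these genes had a median level of 14.2 and 13.3 CPM in WT against 1.33 and 1.53 CPM for the markers, and expression in other cells would hide a small ciliated share. Fewer ciliated cells and lower expression of these genes therefore cannot be told apart, and neither can a fluctuation between libraries, since the KO differentiation replicates differed by a median of 0.428.

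Interferon response genes were called on the same difference with the preset correlation only (median difference -0.58, camera adjusted p = 0.0098; adjusted p = 0.767 with an estimated correlation). Hox genes were called likewise (median difference -0.36, camera adjusted p = 0.0098; adjusted p = 0.767 with an estimated correlation). In differentiation, the median KO effect of Hox genes was -0.41 within number 7 and 0.01 within number 8. Both calls were lost with some single libraries left out, as given above, and no cause was tested.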

How the results depend on the processing

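The stricter filter of at least 5 CPM in 2 libraries, the left-out libraries for gene lists, the list tests on the difference between KO effects, the counts shared by both genotypes and the alternatives for genes outside the naming rule were added after seeing the data. The counts for differentiation against proliferation stayed within 1.5 times the reported values with 1 library left out, ranging from 2431 to 3594 higher and 2751 to 3830 lower in WT and from 2277 to 3074 and 2638 to 3261 in KO. Against a fold of 1.5 they were 2024 and 2011 in WT and 1758 and 1829 in KO, fewer by construction. In KO against WT in proliferation, DESeq2 called 6 genes higher and 5 lower, limma-voom with quality weights 1 higher (Bmp3), and a fit of only the 2 groups, the test against a fold of 1.5 and each left-out library 0 lower. In differentiation DESeq2 called 4 higher and 34 lower and the fit without a count filter 1 lower (Yap1). For the difference between KO effects DESeq2 called 3 higher and 9 lower. The cause was not tested.

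The log2 fold change of Yap1 in proliferation was -2.42 against a fold of 1.5 (adjusted p = 0.0556) and ranged from -2.58 to -2.29 with 1 library left out (adjusted p from 0.0896 to 0.458). In differentiation it was -1.99 with DESeq2 (adjusted p = 2.11e-22) and -1.99 without a count filter (adjusted p = 0.0389), and ranged from -2.15 to -1.85 with 1 library left out (adjusted p from 0.2 to 0.868). The sample numbers 7 and 8 recur in every group, and same-numbered libraries deviated together (correlations of 0.538 to 0.784 across genes), but with 2 pairs and no label that says what a number marks, the main fit has no block. With the replicate block, 1 gene was higher (Bmp3) and 1 lower in proliferation, 3 were lower in differentiation (Cd109, Foxj1 and Yap1, the latter at -1.99, adjusted p = 0.0172). With this block 5 lists passed for the difference between KO effects, and the BMP list in differentiation had an adjusted p of 0.0793.

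With an estimated correlation the lists that passed numbered 0 and 0 for KO against WT in proliferation and differentiation, 1 and 1 for differentiation in WT and KO and 0 for the difference between KO effects. With fry, which does not compare a list with other genes, they numbered 0, 0, 12, 14 and 0. With 1 library left out they ranged from 5 to 9 in proliferation, from 1 to 10 in differentiation, from 4 to 9 for differentiation in WT, from 5 to 8 in KO and from 1 to 7 for the difference. Directions reversed with 1 library left out for the YAP/TAZ-TEAD signature in proliferation (adjusted p = 0.2978 without KO replicate 7 and 0.4252 without WT replicate 8, range 0.2602 to 0.9868). They did so for the difference (0.8831 without KO proliferation replicate 8, range 0.1254 to 0.9975), for cholesterol synthesis in proliferation (0.7195 without KO replicate 8, range 1.812e-11 to 0.8602) and for Hox genes in differentiation (0.9689 without WT replicate 7, range 5.568e-06 to 0.9689). The cause was not tested. Other scalings moved the median fold of all genes by less than 0.03 on the log2 scale. Each of these scalings is relative within a library, so a change in the total amount of mRNA per cell would not be seen. For the single genes examined, 1575 of the values under other settings stayed on the same side of the threshold, 14 no longer passed and 24 newly passed, and with 1 library left out these numbers were 1311, 25 and 0.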

Other observations

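The terms and genes of this part were chosen after their values were seen, from the search over 1891 Gene Ontology terms. On differentiation, genes of fatty acid beta-oxidation, which burns fat in mitochondria and peroxisomes, rose in both genotypes, 30 of 42 in WT and 29 of 42 in KO, with none lower (camera adjusted p = 7.86e-06 and 7.57e-06; adjusted p = 0.46 and 0.545 with an estimated correlation). Cpt1a, which brings fatty acids into mitochondria, went from 91.8 to 346.9 CPM in WT and from 90.8 to 322.4 CPM in KO (edgeR adjusted p = 0.000709 and 0.000995). Lysosome genes had 179 of 358 higher and 43 lower in WT and 148 higher and 43 lower in KO (camera adjusted p = 6.08e-05 and 0.00295; adjusted p = 0.437 and 0.537 with an estimated correlation). Lamp1, a protein of the lysosomal membrane, went from 476.6 to 1430.0 CPM in WT and from 554.4 to 1346 CPM in KO (edgeR adjusted p = 0.000322 and 0.000873).

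Genes of the nuclear pore and of ribosome production fell with the cell cycle genes. Of 57 nuclear pore genes, 46 were lower and 1 higher in WT and 43 lower and 1 higher in KO (camera adjusted p = 4.67e-10 and 1.22e-08; adjusted p = 0.437 and 0.537 with an estimated correlation). Nup210 went from 408.9 to 46.6 CPM in WT and from 377.6 to 46.9 CPM in KO (edgeR adjusted p = 0.000321 and 0.000464). Of 150 genes of ribosomal RNA processing, 121 were lower and 7 higher in WT and 97 lower and 6 higher in KO (camera adjusted p = 1.84e-12 and 5.57e-09; adjusted p = 0.437 and 0.537 with an estimated correlation). The nucleolar protein gene Ncl went from 1056 to 414.1 CPM and from 910.3 to 456.6 CPM (edgeR adjusted p = 0.000285 and 0.00108). Cytosolic ribosome genes themselves had 74 of 80 lower in WT and 59 lower and 2 higher in KO (camera adjusted p = 7.5e-13 and 1.22e-08; adjusted p = 0.469 and 0.624 with an estimated correlation).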
